A study of Mus musculus with 44 samples.

How the data were processed

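Data were the peak lists of 44 libraries, 11 for each of H3K4me1, H3K4me3, H3K27ac and H3K27me3. Per the labels, liver cells of Rosa26-LSL-Cas9-EGFP mice were profiled by a CUT&Tag-type protocol with pAG-Tn5, and hepatocytes were labelled with AAV8-TBG-Cre at 5e11 genome copies per mouse. The diet of 0.1% DDC began 1 week after the virus and lasted 8 to 9 weeks, and cells were fixed lightly with formalin (0.1 to 0.15%). The submitters' processing notes name Bowtie2, Picard, deepTools and MACS2 and the mouse genome build mm10. Versions, settings, controls and the filter applied to the peaks are not given in the sources used here.

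Each list gives the start and end of every peak as deposited by the authors, in bases of mm10. The score of each peak is the authors' own and its definition is not given in the sources used here. The lowest score of a library lay between 2 and 2.09 and peak numbers skip 1.30 to 3.95%, so the authors' deposited lists had been filtered. The score was used only to rank peaks within a list. Of 1341191 peaks, 1210 (0.0902%) on contigs other than the 19 autosomes, X and Y were left out. No list held overlapping peaks. Peak length differed between libraries, with medians of 58 to 486 bp and shortest peaks of 50 to 200 bp. Libraries with a shortest peak under 100 bp, called short-peak libraries here, were late 1 and late 3 for H3K4me1, intermediate 1 and late 1 for H3K4me3, and late 1 for H3K27ac and H3K27me3.

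Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, with 21887 protein-coding genes on the chromosomes used. The plan called for transcription start sites. That table has neither strand nor transcripts, so the plan was departed from and each promoter was placed blind to stage, at the gene end with more H3K4me3 summed over the 11 libraries (12934 genes). Where a region inside the gene (peaks within 1000 bp joined) had more, that region was used (1692 genes). Without H3K4me3 the end was chosen by H3K27ac (693) or H3K4me1 (881), and without any of these both ends were used (5687). Of 12531 genes whose ends differ in H3K4me3 and H3K27ac, 93.5% had the same end chosen by H3K27ac. For 3933 genes no library had a peak in the gene or within 2500 bp. Eef2 had none in any of 44 libraries and Aqp1 had some in 18.

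The groups, comparisons, tests, gene lists and other settings tried were chosen before the data were examined, except where a later choice is stated below. Stage similarity was the Jaccard index of covered bases of each pair of libraries, same-stage mean minus different-stage mean, with 100000 permutations of stage over the 11 libraries, one-sided. For position, regions were the union of peaks over the 11 libraries, kept with peaks in 2 or more. The BEC-specific minus the Hep-specific share with a peak was tested against the order early, intermediate, late over 7 libraries by an exact two-sided permutation test of the covariance. Both were adjusted by Benjamini-Hochberg over 4 marks. The BEC-specific and Hep-specific shares were also tested on their own and adjusted over both shares and all marks.

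Promoter coverage was log2 of the bp covered within 2500 bp on each side plus 100, for protein-coding promoters with a peak in 2 or more libraries. It was fitted with limma (lmFit and eBayes), all 11 libraries of a mark in one fit of 5 stages, with 6 contrasts and an adjusted p (Benjamini-Hochberg) under 0.05 within a contrast. This was run for H3K4me3 and H3K27ac. Where a group has no peak no fold is given. Lists were also adjusted over the list alone.

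List trends used the share of list promoters with a peak within 1000 bp minus that of all protein-coding genes. For H3K4me1 they used the covered percent of 25000 bp on each side, minus that of all genes. The order Hep, early, intermediate, late was tested over 9 libraries by an exact two-sided permutation test and adjusted over all lists and marks. BEC values stand beside them and were not tested, since 2 against 2 libraries give an exact p no lower than 0.333. The 20 lists, with 330 entries and 318 symbols of which 317 are in the gene table, were hepatocyte function, bile acid and xenobiotic, hepatocyte transcription factors, biliary markers, biliary transcription factors, YAP targets, Notch pathway, TGF-beta and EMT, pericentral, periportal, fetal liver, NRF2 and stress, cell cycle, and the positive controls housekeeping and developmental Polycomb targets. Markers of other cell types were stellate and fibroblast, endothelial, macrophage and Kupffer, lymphocyte and neutrophil lists. For promoter states a mark was counted where every library of a stage had a peak within 1000 bp and absent where none had. Gains were compared by Fisher's exact test across genes.

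Genes named in the text came from a fixed rule. It took up to 8 per direction with the largest change among those that passed with no overlap between the libraries of the 2 stages, without Gm and Rik symbols. It added up to 6 passing members per direction of 8 lists, and always Alb, Hnf4a, Cyp7a1, Krt7, Krt19, Spp1, Sox4, Sox9 and the sort markers Epcam and Cd24a. Some genes that this rule names are not reported here.

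Other settings, set beforehand, were the same number of peaks in every library, the stricter 50% of peaks by score, the share of peaks overlapped, peaks covering 50% of a region, regions in 3 or more libraries, a log2 odds ratio with 0.5 added, 500 added in place of 100 bp, other windows (1000, 2500 or 10000 bp), quantile normalization, no filter on promoters, eBayes with trend and robust, the list share alone, H3K27ac by neighbourhood, replicate number as a block, and each library left out in turn. Settings chosen after seeing the data were peaks resized to 500 bp, short-peak libraries left out, gene ends only, H3K4me1 as a ratio to all genes and H3K27me3 at the promoter position or either gene end. Signal tracks and reads were not used here.

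The methods were tested on simulated data. Of 2000 simulated trends without change over 9 libraries 4.6% had p under 0.05. With changes of log2 1, 2 and 3 added to 100 promoters, limma found 4, 34 and 88% for H3K4me3 with 3 false calls, and 1, 51 and 91% for H3K27ac with 7. These values were drawn with normal noise for each gene alone, without the differences in peak length between libraries. The false calls therefore do not measure the error in the real libraries. Nothing in the labels says that replicates come from separate mice, so p-values measure only the spread between these samples. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.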

Results

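Chromatin was profiled by a CUT&Tag-type assay, in which an antibody directs Tn5 cutting to a histone mark, in cells of the mouse liver at 5 stages between hepatocyte and biliary identity. The marks were H3K4me3 (active promoters), H3K27ac (active promoters and enhancers), H3K4me1 (enhancers) and H3K27me3 (Polycomb-repressed regions), with 11 libraries per mark and 44 in all. Normal hepatocytes (Hep, n = 2 libraries per mark) came from mice on no DDC. The other stages came from mice given 0.1% DDC, a toxin that injures the bile ducts, for 8 to 9 weeks. Hepatocytes carrying EGFP through AAV8-TBG-Cre were sorted as early (CD24-negative, n = 2), intermediate (CD24-positive and EPCAM-negative, n = 2) and late (positive for CD24 and EPCAM, n = 3) cells. Biliary epithelial cells (BEC, n = 2) were EGFP-negative and EPCAM-positive. Libraries held 19356 to 33762 peaks for H3K4me3, 23511 to 51807 for H3K27ac, 12785 to 77991 for H3K4me1 and 2343 to 16597 for H3K27me3. Read depth is unknown. Hep cells were purified on a gradient and all other cells were sorted, so normal diet and isolation cannot be told apart from stage in any comparison with Hep.

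All promoter values below are base pairs (bp) covered by peaks within 2500 bp of the promoter, as mean ± SD over the libraries of a stage, with n as given above. Their adjusted p come from limma. Where 1 library is left in a stage, that lone sample is assumed to vary like the other groups. Of the sort markers, Cd24a had no H3K4me3 peak in Hep or early cells, 1027 ± 498 bp in intermediate, 911 ± 443 bp in late and 1248 ± 91.2 bp in BEC libraries. Epcam did not separate the gates, with 133 ± 188 bp in Hep, 232 ± 329 bp in early, 484 ± 104 bp in EPCAM-negative intermediate, 456 ± 331 bp in EPCAM-positive late and 1361 ± 96.2 bp in BEC libraries. Of 20 housekeeping promoters, 87.5 ± 3.54% carried H3K4me3 in early and 88.3 ± 2.89% in late libraries. Of 26 developmental Polycomb targets 17.3 ± 13.6% carried H3K27me3 in Hep, 26.9 ± 17.6% in late and 1.92 ± 2.72% in BEC libraries. Most targets of this positive control thus had no H3K27me3 peak, so a missing H3K27me3 peak does not show that the mark was absent. Shares of a list count promoters with a peak within 1000 bp. No neutrophil promoter had an H3K4me3 peak within that distance in any stage, macrophage promoters went from 4.55 ± 6.43% in Hep to 9.09 ± 0% in late and BEC libraries, and lymphocyte promoters stood at 18.2 ± 0% in both Hep and late libraries. The stellate and fibroblast share was 8.33 ± 0% in Hep, 33.3 ± 0% in intermediate and 25.0 ± 8.33% in late libraries. The endothelial share was 16.7 ± 0% in Hep, 33.3 ± 11.8% in intermediate and 27.8 ± 4.81% in late libraries.

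Averaged over all pairs, H3K27ac and H3K4me1 peaks overlapped more within than between stages. For H3K27ac the mean overlap (Jaccard index of covered bases) was 0.404 within and 0.278 between stages, a difference of 0.126 (one-sided permutation test, adjusted p = 0.00236). Not every stage showed it, since late libraries overlapped each other by 35.9% and intermediate ones by 38.9%. Mean overlap with Hep was 30.2% for early, 28.0% for intermediate, 20.0% for late and 17.8% for BEC libraries. Overlap of H3K27ac with BEC was 19.8% for early, 33.2% for intermediate and 34.2% for late libraries. For H3K4me1 the difference was 0.0655 (permutation, adjusted p = 0.0338) and rested on the Hep pair (43.7%). Early libraries overlapped each other by 13.9% and intermediate ones by 15.5%, late libraries overlapped each other by 15.3% and intermediate ones by 16.9%, and BEC libraries overlapped each other by 12.1% and late ones by 14.1%. It was 0.0234 without Hep 1 (permutation, adjusted p = 0.17), 0.0233 without Hep 2 (0.18) and 0.0645 without early 1 (0.0736). H3K4me3 (0.0521, permutation, adjusted p = 0.079) and H3K27me3 (0.0225, permutation, adjusted p = 0.0551) did not pass.

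The next comparison asked where the reprogramming cells lie between hepatocytes and biliary cells. Regions with a peak in both Hep and no BEC library, or the reverse, were taken as Hep-specific or BEC-specific. H3K27ac at BEC-specific regions was listed in 17.7 ± 6.37% of regions in early, 55.9 ± 2.50% in intermediate and 64.8 ± 6.06% in late libraries, a rise of 22.7 points per stage (exact two-sided permutation test, adjusted p = 0.0191). Over the same stages H3K27ac at Hep-specific regions fell from 42.9 ± 11.3% through 37.2 ± 7.72% to 19.4 ± 6.66%, by 12.1 points per stage (exact, adjusted p = 0.0457). The H3K4me3 shares of BEC-specific regions were 21.1 ± 5.51%, 50.5 ± 8.75% and 55.9 ± 11.4% (exact, adjusted p = 0.0457), and those of Hep-specific regions were 41.6 ± 7.85%, 31.8 ± 4.71% and 17.5 ± 6.10% (exact, adjusted p = 0.0254). H3K4me1 rose at 10502 BEC-specific regions by 20.2 points per stage (exact, adjusted p = 0.0191), while its change at 28692 Hep-specific regions was −6.71 points (exact, adjusted p = 0.316). Early lists also missed regions shared by all Hep and BEC libraries, which can add to the BEC-specific rise. For H3K27ac 77.1 ± 8.10% of these were listed in early, 95.6 ± 3.11% in intermediate and 92.6 ± 4.94% in late libraries. The H3K4me1 share was 61.7 ± 32.6% in early and 78.0 ± 15.4% in late libraries, and that of H3K4me3 95.9 ± 1.81% and 96.55 ± 2.5%.

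The BEC-specific minus the Hep-specific share placed every early library on the hepatocyte side and every late library on the biliary side for H3K4me1, H3K4me3 and H3K27ac. It moved by 26.9 points per stage for H3K4me1, 28.8 for H3K4me3 and 34.7 for H3K27ac, each at the smallest p the 7 libraries allow (exact, p = 0.00476, adjusted p = 0.00635). For H3K27ac the stage means were −25.2 ± 4.93, 18.7 ± 5.22 and 45.3 ± 0.934 points. H3K27me3 moved by 9.51 points per stage and did not pass (exact, p = 0.081), although it did without BEC 2 (13.6 points, adjusted p = 0.00952), without Hep 2 (12.6 points, 0.0381) or without BEC 1 (9.41 points, 0.0476), against 1.55 points without Hep 1. With peaks required to cover 50% of a region the shift no longer passed for H3K4me1 (12.2 points per stage) and H3K4me3 (16.9). With the 2 short-peak libraries of H3K4me1 or H3K4me3 or the 1 of H3K27ac left out, the slopes were 30.0, 31.6 and 35.5 points with exact adjusted p of 0.0667, 0.0889 and 0.0667. Each rests on the smallest exact p that the remaining libraries allow (0.0333, 0.0667 and 0.0222), so the loss in these 3 settings says nothing about the shift.

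**Figure D1:**
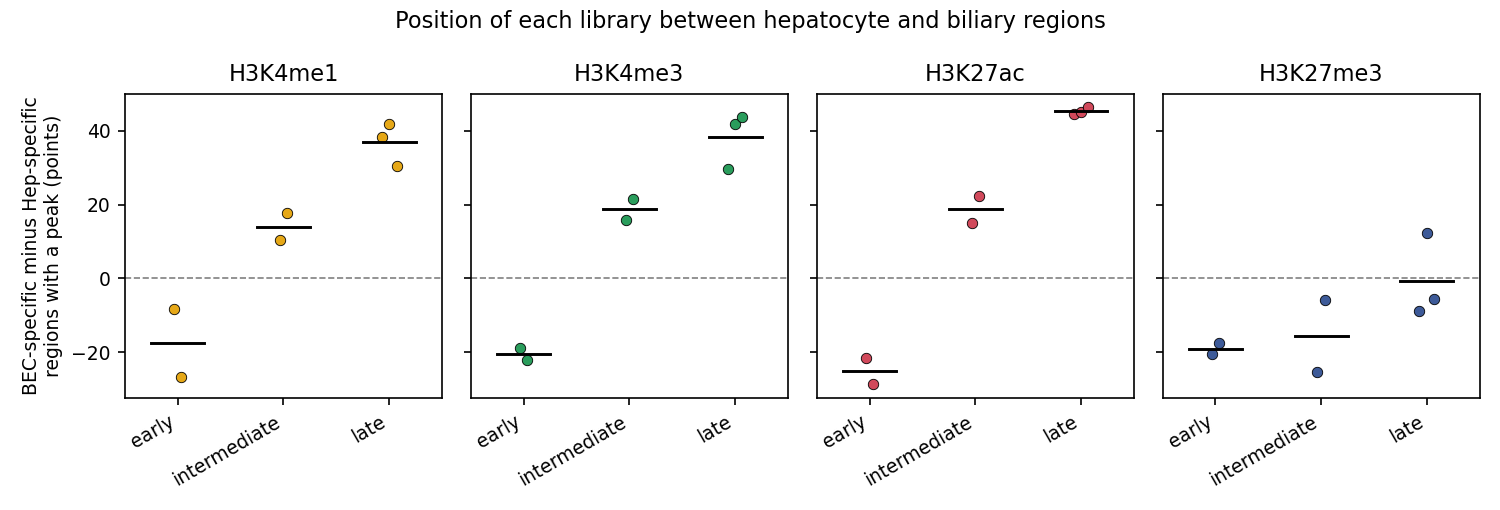
Position of each early, intermediate and late library between hepatocyte and biliary regions for 4 histone marks; the y axis is the percent of BEC-specific minus the percent of Hep-specific regions with a peak, in points, each dot is a library and each bar a stage mean. For H3K27ac the means rise from −25.2 in early to 45.3 points in late libraries.

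Early cells, which are EGFP-positive and still CD24-negative, were compared with normal hepatocytes. The bile acid and xenobiotic enzymes Cyp8b1 (chromosome 9, 121914356 to 121916305, mm10), a sterol hydroxylase, and Cyp2f2, a periportal cytochrome, had no H3K4me3 peak in early libraries against 1632 ± 695 and 986 ± 240 bp in Hep (adjusted p = 0.00276 and 0.00389). Ces1f, a liver carboxylesterase (chromosome 8, 93256236 to 93279766), and Hsd3b5, a steroid dehydrogenase, likewise went from 1746 ± 216 and 1138 ± 61.5 bp to no peak (adjusted p = 0.00136 and 0.00276). The biliary genes Ddr1, a collagen receptor, and Anxa2 had 981 ± 209 and 885 ± 467 bp in early libraries and no peak in Hep (adjusted p = 0.00706 and 0.0155), as did Osbpl3 (1224 ± 108 bp, 0.00663) and Pdgfb (1055 ± 7.07 bp, 0.00831). The keratins Krt19 and Krt7 had no peak in either stage. Sox9 (1184 ± 168 against 1310 ± 84.2 bp), a regulator of biliary fate, carried H3K4me3 already in Hep, and Hnf4a, the hepatocyte regulator, had 1326 ± 279 against 1664 ± 265 bp (adjusted p = 1 for each).

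Of 28 biliary markers tested for H3K4me3, 3 rose, 0 fell and 25 did not pass, with 6 higher when adjusted over the list alone. Of 20 bile acid and xenobiotic genes 2 fell (3 adjusted over the list alone), and of 30 hepatocyte function genes 0 passed (limma, 0 adjusted over the list alone). Among 22 YAP targets Ccn2 was higher (494 ± 37.5 bp against no peak, adjusted p = 0.0451) and Ccn1 lower (no peak against 989 ± 18.4 bp, 0.0225), the latter not after quantile normalization or with resized peaks. None of 12 biliary and 13 hepatocyte transcription factors, 14 Notch pathway and 16 TGF-beta and EMT genes passed over all genes (limma). Over the whole genome 57 promoters gained and 52 lost H3K4me3 out of 14326, and 774 had an unadjusted p under 0.05. With peaks resized to one width the split was 388 higher and 129 lower. Of these 109 calls 0 were left without Hep 2, early 1 or early 2 and 1 without Hep 1, while 243 were called without late 1.

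H3K27ac was lower at many more promoters of early cells. Epas1, a hypoxia factor (chromosome 17, 86753864 to 86833410), went from 1414 ± 240 bp in Hep to no peak (adjusted p = 0.002), Epha2, a receptor kinase, from 1236 ± 125 bp (0.00246). Other losses were at Arg1, the urea cycle arginase, from 707 ± 32.5 bp (0.00199) and Cyp2e1 from 434 ± 89.1 bp (0.00224, not passing after quantile normalization). Cyp8b1, without H3K4me3 in early cells, had 469 and 730 bp of H3K27ac in Hep, 0 and 385 bp in early and 261 and 191 bp in intermediate libraries. Higher from no peak in Hep were Pdgfb (571 ± 36.1 bp, 0.00209), Psca (609 ± 29.7 bp, 0.00198) and Cubn (684 ± 103 bp, 0.0035). So were the biliary markers Anxa2 (477 ± 102 bp, 0.00348), Ddr1 (372 ± 85.6 bp, 0.00789), Aqp1 (312 ± 213 bp, 0.0083) and Prom1 (284 ± 61.5 bp, 0.0083). Of 28 biliary markers 7 rose, 1 fell and 20 did not pass (7 and 2 adjusted over the list alone). Of 30 hepatocyte function genes 10 fell (11 adjusted over the list alone, 1 after quantile normalization), of 18 bile acid and xenobiotic genes 7 (8, 0), and of 13 hepatocyte transcription factors 4 (6, 0). Of 21 YAP targets 1 rose and 7 fell, of 13 Notch pathway genes 1 and 3, and of 15 TGF-beta and EMT genes 1 and 5. After quantile normalization 1 rose and 0 fell in each of these 3 lists. Of 19 housekeeping promoters 6 fell, with 0 of the housekeeping calls left after quantile normalization.

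Over all 13485 tested promoters 128 had more and 3245 less H3K27ac in early cells, with a median of −0.91 on the log2 scale. After quantile normalization, which sets that median to 0.05, 159 were higher and 65 lower, and with peaks resized to one width 138 and 918. Covered length was 14.1 ± 0.721 Mb in Hep and 8.41 ± 0.0856 Mb in early H3K27ac libraries. The count of 3373 was 285 without Hep 2, 502 without Hep 1 and 2176 without early 1, with Ddr1, Aqp1 and Prom1 lost without either Hep library.

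Intermediate cells, the CD24-positive and EPCAM-negative fraction, were compared with early cells. Among the genes that lost H3K4me3, Nr1i3, a xenobiotic receptor (chromosome 1, 171213934 to 171218845), went from 1280 ± 9.19 bp in early cells to no peak (adjusted p = 0.00274), Akr1d1, a bile acid synthesis reductase, from 1300 ± 118 bp (0.00274), Urad from 1175 ± 55.2 bp (0.00274), Car5a, a mitochondrial carbonic anhydrase, from 1106 ± 238 bp (0.00291). Fabp1, the liver fatty acid carrier, fell from 946 ± 296 bp to no peak (adjusted p = 0.0167). Agxt fell from 616 ± 44.6 bp to no peak (0.0307) and Hao1 from 809 ± 470 to 30.5 ± 43.1 bp (log2 −2.74, 0.04), both enzymes of glyoxylate metabolism. H3K4me3 was present where early cells had no peak at Cdh6, a cadherin (777 ± 191 bp, 0.029), Zeb2, an EMT regulator (796 ± 505 bp, 0.029), and Wnt7a (671 ± 315 bp, 0.0486), besides the sort marker Cd24a. Zeb2 also had an H3K4me3 peak within 1000 bp in 2 of 2 Hep libraries, so its mark was not new over the series. Krt19 had 212 ± 94.8 bp and Krt7 128 ± 87.0 bp against no peak in early cells and did not pass (adjusted p = 0.198 and 0.529), nor did Cyp7a1, the rate-limiting enzyme of bile acid synthesis (no peak against 263 ± 5.66 bp, 0.0852).

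Of 20 bile acid and xenobiotic genes 3 lost H3K4me3 and 17 did not pass, with 9 lower when adjusted over the list alone. Of 28 biliary markers, which include the sort marker Cd24a, 1 gained it, with 8 adjusted over the list alone. A gain at Cd24a is tied to the gate that separates these 2 stages. Of 13 hepatocyte transcription factors Nr1i3 fell, of 22 YAP targets 0 passed over all genes (limma) and 3 rose adjusted over the list alone, and of 30 hepatocyte function genes the same counts were 0 (limma) and 4 lower. Beside these, the stellate and fibroblast promoters moved too, with 0 of 4 passing over all genes (limma) and 3 higher adjusted over the list alone. Genome-wide 10 promoters rose and 26 fell, 1104 had an unadjusted p under 0.05, and the median of all promoters was −0.35. The split was 224 and 186 after quantile normalization and 666 and 54 with resized peaks. The count of 36 was 0 without early 1 or early 2, 5 and 9 without an intermediate library, 10 without late 3, 18 without Hep 1 or Hep 2 and 387 without late 1.

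With the listed peaks the median H3K27ac over all promoters was higher in intermediate cells, and the lists were not tested against that rise. An equal number of peaks per library gave a median change of 0, with 120 promoters higher and 150 lower. Ptpn14 (625 ± 125 bp, adjusted p = 0.0124) and Ankrd1 (356 ± 31.8 bp, 0.0181), both YAP targets, had no peak in early cells, nor had Dcdc2a, a ciliary gene (476 ± 3.54 bp, 0.014), Lfng, a Notch modifier (428 ± 134 bp, 0.0131), and Klf5, an epithelial regulator (322 ± 94.8 bp, 0.0166). Shmt2 (488 ± 154 bp, 0.0124), of folate metabolism, and Pltp (358 ± 139 bp, 0.0166), a lipid transfer protein, went from these early values to no peak. Of 21 YAP targets 5 rose and 16 did not pass (5 adjusted over the list alone, 1 after quantile normalization). Of 28 biliary markers 5 rose (5 adjusted over the list alone, 0 after quantile normalization), as did 2 biliary transcription factors, 2 of 19 cell cycle genes and 1 gene each of the Notch pathway, TGF-beta and EMT, bile acid, fetal liver and pericentral lists. Of 3 stellate genes 1 fell and 0 of 30 hepatocyte function genes passed (limma). Genome-wide 680 promoters rose and 37 fell, with a median of 0.46 over all promoters, 2722 under an unadjusted p of 0.05, and 64 and 89 after quantile normalization. The count of 717 was 0 without early 1 or intermediate 1, 287 without Hep 1 or Hep 2 and 1213 without early 2.

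Late cells, which have gained EPCAM, were compared with intermediate cells. The mean H3K4me3 length was 467 ± 177 against 212 ± 94.8 bp at Krt19, 297 ± 112 against 128 ± 87.0 bp at Krt7 and 467 ± 343 against 231 ± 115 bp at Spp1, the osteopontin gene (adjusted p = 1 for each). H3K27ac at Krt7 was 242 ± 67.9 bp against no peak (adjusted p = 0.13). No promoter passed for H3K4me3 (0 in limma, 241 with an unadjusted p under 0.05) or H3K27ac (0 in limma, 734). Adjusted over the list alone, 3 hepatocyte function and 3 periportal genes lost H3K4me3. Resized peaks gave 52 higher and 51 lower promoters for H3K4me3 and 88 and 82 for H3K27ac, and 6 passed for H3K4me3 without late 1.

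Late cells were also set against normal hepatocytes, the whole path. Late libraries carried H3K4me3 where Hep had no peak at Itgb8, an integrin that activates TGF-beta (997 ± 397 bp, adjusted p = 0.000731, chromosome 12, 119162803 to 119238276), Cldn7, a tight junction protein (953 ± 393 bp, 0.000815), Bmp6 (1061 ± 526 bp, 0.00147), Ccn2 (977 ± 479 bp, 0.00142) and St14, an epithelial protease (850 ± 386 bp, 0.00307). The biliary keratins Krt19 (467 ± 177 bp, 0.00415) and Krt7 (297 ± 112 bp, 0.0155), the chloride channel Cftr (719 ± 430 bp, 0.00381) and Spp1 (467 ± 343 bp, 0.0203) were likewise marked in late cells alone of these 2 stages. Each of these 4 calls, and that of Cyp7a1, was lost without Hep 1 or Hep 2 (limma, adjusted p of 0.0521 to 0.185), and Spp1 also without late 2 (0.051) or late 3 (0.0759). In the other direction Hpd (2007 ± 301 bp in Hep, 0.000164), of tyrosine breakdown, Ido2 (2039 ± 38.2 bp, 0.000271), Mbl2 (1822 ± 8.49 bp, 0.000164), the lectin of complement, Nr1i3 (1412 ± 131 bp, 0.000201) and Cyp7a1 (342 ± 26.2 bp, 0.00484) had no peak in late cells. Only 1 of 3 late libraries had a peak at Cyp8b1 (18.7 ± 32.3 against 1632 ± 695 bp, log2 −3.84, 0.000333), the bile acid ligase Slc27a5 (44.3 ± 76.8 against 1797 ± 2.83 bp, log2 −3.84, 0.000367) and the bile acid uptake transporter Slc10a1 (80.7 ± 140 against 1664 ± 47.4 bp, log2 −3.55, 0.00266). Sox9 (483 ± 162 against 1310 ± 84.2 bp, 0.125) and Alb (307 ± 247 against 314 ± 38.2 bp, 0.806) did not pass.

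By list, 13 of 28 biliary markers gained H3K4me3, 0 lost it and 15 did not pass (18 higher and 2 lower adjusted over the list alone). Of 20 bile acid and xenobiotic genes 16 lost it (19 adjusted over the list alone, 9 with resized peaks), of 30 hepatocyte function genes 10 (18, 6), of 12 periportal genes 7 (8 adjusted over the list alone) and of 14 pericentral genes 4. YAP targets went 5 up and 1 down of 22 (6 and 2 adjusted over the list alone). Biliary transcription factors went 2 up of 12 (5 and 4) and TGF-beta and EMT genes 1 up, Vim, and 1 down, Smad3, of 16 (1 and 4). Of 14 Notch pathway genes 0 passed (limma), with 2 higher adjusted over the list alone. Beside these lists 1 of 4 stellate genes rose, 1 of 7 fetal liver genes fell, and 0 of 5 endothelial, 2 macrophage, 3 lymphocyte and 1 neutrophil genes passed (limma). Genome-wide 440 promoters rose and 466 fell, with a median of −0.66 over all promoters and 3402 under an unadjusted p of 0.05. With peaks resized to one width 1942 rose and 227 fell, of which 416 and 185 were among the calls above. Counts ranged from 155 without Hep 2, 170 without Hep 1 and 435 without late 3 to 1506 without late 1.

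Late libraries had H3K27ac peaks and Hep none at S100a6 (673 ± 163 bp, adjusted p = 0.000967), S100a3 (792 ± 118 bp, 0.000931), Plaur, the urokinase receptor (725 ± 219 bp, 0.00281), Lfng (487 ± 136 bp, 0.00173), Ptpn14 (432 ± 89.0 bp, 0.00157), Krt19 (296 ± 44.9 bp, 0.0097) and Krt7 (242 ± 67.9 bp, 0.00609). Hal, of histidine breakdown (989 ± 83.4 bp in Hep, 0.000931), Arg1 (707 ± 32.5 bp, 0.000931), Cyp2e1 (434 ± 89.1 bp, 0.00116) and the Notch effector Hes1 (964 ± 0.707 bp, 0.0103) had none in late cells. Alb fell from 363 ± 39.6 to 35.3 ± 61.2 bp (log2 −1.86, adjusted p = 0.00867). Krt19, Krt7, Hes1 and Alb were lost without Hep 1 or Hep 2 (limma, adjusted p of 0.0782 to 0.0973), and Plaur without Hep 2 (0.0523). Biliary markers went 14 up and 2 down of 28 (16 and 2 adjusted over the list alone), and YAP targets 8 and 5 of 21 (8 and 8, and 7 and 1 after quantile normalization). Biliary transcription factors went 2 up and 4 down of 12 (2 and 4, and 4 and 1 after quantile normalization). Notch pathway genes went 4 and 4 of 13 (4 and 5, and 4 and 1 after quantile normalization). Lower were 16 of 30 hepatocyte function genes (19 adjusted over the list alone, 9 after quantile normalization, 4 with resized peaks), 10 of 18 bile acid genes (10, 8, 6), and 6 of 13 hepatocyte transcription factors (7, 4, 2). So were 8 of 12 periportal, 4 of 14 NRF2 and stress and 2 of 19 housekeeping genes (4, 1 and 0 with resized peaks). Of 13485 promoters 683 rose and 2819 fell, with a median of −0.81 and 6064 under an unadjusted p of 0.05, against 859 and 647 after quantile normalization and 723 and 438 with resized peaks. Without Hep 2 the count of 3502 was 91, without Hep 1 155, without late 1 1803 and without late 3 1883.

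BEC were compared with late cells, the nearest stage by sort. H3K4me3 in BEC was present where late cells had none at Sftpd, a surfactant collectin (1490 ± 184 bp, adjusted p = 0.000819, chromosome 14, 41172212 to 41185198), Anxa1 (1087 ± 36.8 bp, 0.00111) and Cldn8, a tight junction protein (1356 ± 78.5 bp, 0.00111). It was higher at Mmp7, a matrix protease of injured ducts (1611 ± 243 against 47.7 ± 82.6 bp, log2 3.66, 0.00186), and the integrin Itgb6 (1600 ± 564 against 91.3 ± 158 bp, log2 3.41, 0.00777). H3K4me3 was listed in late cells with no BEC peak at Prlr (327 ± 81.5 bp, 0.0398), Inhbe, a hepatocyte activin (403 ± 122 bp, 0.0208), and Mab21l2 (516 ± 245 bp, 0.0212). Krt19 (1556 ± 125 against 467 ± 177 bp, 0.159), Krt7 (1167 ± 1.41 against 297 ± 112 bp, 0.115) and Epcam (1361 ± 96.2 against 456 ± 331 bp, 0.266) did not pass. Mmp7 and Itgb6 were the 2 biliary markers of 28 that rose (12 adjusted over the list alone, 4 after quantile normalization, 0 with resized peaks). Itgb6, which is in both lists, was also the 1 of 16 TGF-beta and EMT genes that rose. Of 30 hepatocyte function genes 0 passed (limma), with 4 lower adjusted over the list alone. Genome-wide 96 promoters rose and 6 fell, with a median of 0.79 and 2462 under an unadjusted p of 0.05, against 134 and 110 after quantile normalization and 102 and 295 with resized peaks. The count of 102 was 0 without BEC 1, 3 without BEC 2, 67 without either early library and 228 without late 1.

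H3K27ac of BEC and late cells differed at 66 promoters higher and 24 lower in BEC, with 1044 under an unadjusted p of 0.05. Ctse, an aspartic protease (578 ± 79.2 bp, adjusted p = 0.0215), Dsg1b, a desmosome cadherin (570 ± 41.0 bp, 0.0081), and St14 (317 ± 146 bp, 0.0221) had no peak in late cells. Cyp27a1, of bile acid synthesis (543 ± 204 bp, 0.0224), Pla2g12b (630 ± 264 bp, 0.0215) and Hnf4a at its position inside the gene (309 ± 144 bp, 0.0443) were marked in late cells and had no peak in BEC. At the gene end Hnf4a had H3K27ac in both, at 464 ± 127 bp in BEC and 285 ± 152 bp in late libraries (log2 0.61). St14 was the 1 biliary marker of 28 that rose, and Cyp27a1 and Hnf4a were the bile acid gene and hepatocyte transcription factor that fell, beside pericentral Rnf43 and periportal Hsd17b13. Quantile normalization gave 131 higher and 108 lower and resized peaks 135 and 223, and the count of 90 was 0 without late 3, BEC 1 or BEC 2, 3 without Hep 1 or Hep 2 and 24 without late 2.

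BEC were last compared with normal hepatocytes, the ends of the series. BEC libraries carried H3K4me3 with no Hep peak at Krt19 (1556 ± 125 bp, adjusted p = 0.000383, chromosome 11, 100140810 to 100145926), Krt7 (1167 ± 1.41 bp, 0.000389, chromosome 15, 101412403 to 101427806), and Sctr, the secretin receptor (1596 ± 158 bp, 0.000533). The same held for Itgb4 (1648 ± 115 bp, 0.000675), Mmp7 (1611 ± 243 bp, 0.000383), Spp1 (824 ± 173 bp, 0.00207), the gap junction gene Gja1 (1886 ± 255 bp, 0.000383) and Sparc (2022 ± 316 bp, 0.00062). Hepatocyte genes with no BEC peak included Serpinc1, antithrombin (2116 ± 286 bp in Hep, 0.000383), Fabp1 (2041 ± 168 bp, 0.000383), Hpd (2007 ± 301 bp, 0.000383), Slc10a1 (1664 ± 47.4 bp, 0.000829) and Slc27a5 (1797 ± 2.83 bp, 0.000383). Of 28 biliary markers 23 gained H3K4me3, 0 lost it and 5 did not pass (25 higher adjusted over the list alone, 15 with resized peaks). Of 20 bile acid and xenobiotic genes 16 fell (16 adjusted over the list alone, 8 with resized peaks), of 30 hepatocyte function genes 17 (18, 11), of 13 hepatocyte transcription factors 4 (4, 1), of 12 periportal genes 8 and of 14 pericentral genes 4, with 1 higher. YAP targets went 7 up and 1 down of 22 (8 and 1 adjusted over the list alone), with Ccn2 at 1594 ± 181 bp and Ankrd1 at 932 ± 285 bp (0.000738) against no Hep peak. Notch pathway genes went 5 up of 14 (6 and 1), with Dll4 at 1002 ± 506 bp against no Hep peak (0.00086) and Nrarp at 1184 ± 151 against 85.5 ± 121 bp (log2 2.96, 0.00689, and 0.115 without Hep 1). Biliary transcription factors went 4 up of 12 (6 and 1) and TGF-beta and EMT genes 3 up and 2 down of 16. After quantile normalization the Notch pathway split was 3 up and 2 down and that of TGF-beta and EMT genes 2 up and 5 down. With resized peaks 2 Notch pathway genes, 5 YAP targets and 3 biliary transcription factors rose, and TGF-beta and EMT genes went 1 up and 1 down. Beside them 2 of 4 stellate, 1 of 5 endothelial, 1 of 20 cell cycle and 1 of 12 Polycomb target genes rose. Genome-wide 1311 promoters rose and 490 fell of 14326, with 923 and 818 after quantile normalization, and the count of 1801 was 1009 without Hep 1.

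For H3K27ac, BEC had peaks and Hep none at Krt19 (652 ± 41.7 bp, adjusted p = 0.00247), Krt7 (531 ± 163 bp, 0.0016), Lfng (684 ± 79.9 bp, 0.00132), Src (944 ± 318 bp, 0.00111) and Plaur (992 ± 209 bp, 0.00188). Hep had peaks and BEC none at the clotting gene F10 (1954 ± 69.3 bp, 0.0022), Klb, a co-receptor for FGF hormones (1378 ± 0.707 bp, 0.0016), the urea cycle enzyme Cps1 (848 ± 43.1 bp, 0.00353), Cyp27a1 (887 ± 7.07 bp, 0.00183), Alb (363 ± 39.6 bp, 0.00485, and 0.0502 without Hep 1) and the EMT regulator Snai2 (936 ± 153 bp, 0.00123). Biliary markers went 17 up and 1 down of 28 (19 and 2 adjusted over the list alone), Notch pathway genes 4 and 4 of 13 (4 and 6), YAP targets 6 and 4 of 21 (6 and 7, and 6 and 1 after quantile normalization), and TGF-beta and EMT genes 2 and 4 of 15. Lower were 18 of 30 hepatocyte function genes (25 adjusted over the list alone, 13 after quantile normalization, 5 with resized peaks), 13 of 18 bile acid genes (13, 9, 7), and 7 of 13 hepatocyte transcription factors (8, 6, 3). So were 9 of 12 periportal, 6 of 11 pericentral and 4 of 19 housekeeping genes (6, 3 and 0 with resized peaks), and 0 housekeeping calls were left after quantile normalization. Of 13485 promoters 928 rose and 2143 fell, with a median of −0.70, against 1175 and 963 after quantile normalization and 713 and 575 with resized peaks. The count of 3071 was 725 without Hep 2, 848 without Hep 1, 1368 without BEC 2 and 1682 without BEC 1.

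The gene lists were then followed over the ordered stages Hep, early, intermediate and late, as the share of list promoters with a peak less that of all genes. H3K4me3 stood at 100 ± 0% of 20 bile acid and xenobiotic promoters in Hep, 85.0 ± 7.07% in early, 50.0 ± 14.1% in intermediate, 36.7 ± 16.1% in late and 25.0 ± 7.07% in BEC libraries, a slope of −24.1 points per stage (exact two-sided permutation test, adjusted p = 0.0106). Its H3K27ac share went from 82.5 ± 3.54% in Hep to 23.3 ± 5.77% in late libraries (−19.6 points per stage, exact p = 1.32e-04, the smallest the 9 libraries allow, adjusted p = 0.00529). Periportal genes held H3K4me3 at 95.8 ± 5.89% in Hep, 87.5 ± 5.89% in intermediate and 47.2 ± 9.62% in late libraries (−18.0 points, exact, adjusted p = 0.0106). Their H3K27ac fell by 13.4 points per stage (exact, adjusted p = 0.00529). Of the periportal genes Hal, Pck1, Ass1, Cps1 and Arg1 are also in the hepatocyte function list and Cyp2f2 in the bile acid list. Hepatocyte function genes fell by 11.4 points per stage in H3K4me3 (exact, adjusted p = 0.0166), with 85.0 ± 2.36% in Hep, 80.0 ± 0% in intermediate and 57.8 ± 11.7% in late libraries, and by 10.1 points in H3K27ac (exact, adjusted p = 0.0106). Biliary markers rose in H3K4me3 from 25.0 ± 11.8% in Hep and 38.3 ± 7.07% in early to 80.0 ± 4.71% in intermediate and 82.2 ± 8.39% in late libraries (18.8 points, exact, adjusted p = 0.0106), and in H3K27ac by 14.9 points (0.0106). The stellate and fibroblast share of H3K4me3, given above, had a slope of 5.11 points (exact, adjusted p = 0.104).

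YAP targets rose by 10.4 points in H3K4me3 (exact, adjusted p = 0.0218) and 10.3 points in H3K27ac (0.0423), with H3K4me3 at 50.0 ± 6.43% in Hep, 59.1 ± 6.43% in early, 88.6 ± 3.21% in intermediate and 83.3 ± 2.62% in late libraries. In BEC 16 of 22 YAP targets had H3K4me3 in both libraries. Their H3K4me3 trend was lost without Hep 1, Hep 2, early 2, intermediate 2 or late 1 (exact adjusted p 0.0504 to 0.0827), and the H3K27ac trend on leaving out any 1 of 6 libraries (0.0688 to 0.116). Pericentral genes (−5.80 points, exact, adjusted p = 0.0423), NRF2 and stress genes (−3.57, 0.0166) and housekeeping genes (−2.11, 0.0218) fell in H3K4me3 relative to all genes, whose share was 51.2% in Hep and 55.9% in late libraries. The pericentral genes Cyp2e1 and Cyp1a2 are also in the bile acid list. Both had H3K4me3 in 2 of 2 Hep and 0 of 3 late libraries, and the pericentral trend without them was not tested. The pericentral trend was lost without Hep 1, Hep 2, early 1, early 2 or intermediate 1 (0.0619 to 0.194) and was −2.97 points without late 1. The NRF2 trend was lost without Hep 2 (exact, adjusted p = 0.0578) and the housekeeping trend without Hep 1 (0.0827) or late 1 (0.0706). Slopes in H3K27ac that did not pass over all lists and marks were 6.62 points for Notch pathway genes (exact, adjusted p = 0.0542), −6.23 for hepatocyte transcription factors (0.0538), 4.07 for TGF-beta and EMT (0.0716), 0.533 for biliary transcription factors (0.875), 6.74 for cell cycle (0.0648) and 0.841 for fetal liver genes (0.831). Those of other cell types were −0.309 for macrophage (0.906), 1.71 for lymphocyte (0.545), −3.06 for neutrophil (0.212), 1.69 for endothelial (0.689) and −0.625 for stellate and fibroblast genes (0.853). Measured by neighbourhood the stellate and fibroblast slope was 0.370 and passed.

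H3K27me3 moved the other way over the biliary marker list, but not at each of its members. Its lists were short in BEC (5737 and 2343 peaks), where 1.77% of all promoters had a peak against 9.36% in Hep. It was listed at 38.3 ± 16.5% of 30 biliary marker promoters in Hep, 23.3 ± 0% in early, 13.3 ± 9.43% in intermediate, 13.3 ± 3.33% in late and 0 ± 0% in BEC libraries, a slope of −7.44 points per stage against all genes (exact, adjusted p = 0.0166). YAP targets (−4.68 points, exact, adjusted p = 0.0166), Notch pathway genes (−4.94, 0.0423) and cell cycle genes (−3.55, 0.0423) also fell, from 20.5 ± 9.64%, 21.4 ± 10.1% and 15.0 ± 7.07% in Hep to 4.55 ± 4.55%, 4.76 ± 4.12% and 0 ± 0% in late libraries. Of the 4 trends 0 passed without Hep 2 (exact adjusted p 0.0578 to 0.146), and the Notch pathway trend was lost on leaving out any 1 of 7 libraries and the cell cycle trend any 1 of 6. Polycomb targets had a slope of 5.32 points (exact, adjusted p = 0.261) and biliary transcription factors −0.538 points (0.737). Among the biliary markers Krt19 and Dmbt1 went against their list, with no H3K27me3 peak in Hep and a peak in 2 of 3 late libraries.

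H3K4me1 was measured as the percent of the 25000 bp on each side of a promoter covered by peaks. Relative to all genes it rose around stellate and fibroblast genes (0.42 points per stage, exact p = 3.97e-04, adjusted p = 0.0106), where coverage was 0.28 ± 0.162% in Hep and 0.54 ± 0.281% in late libraries while that of all genes went from 1.56 to 0.443%. Macrophage genes (0.197 points, exact, adjusted p = 0.0423), housekeeping genes (−0.335, 0.0166) and cell cycle genes (−0.294, 0.0166) passed too. With the list share alone the macrophage slope was −0.1145, so its rise came from the fall of all genes. A difference in points can also shrink as coverage of all genes falls. The housekeeping and cell cycle falls are therefore not read as particular to these lists. The macrophage trend was lost on leaving out any library except early 1, the housekeeping trend any 1 of 5 and the cell cycle trend any 1 of 3 (exact adjusted p 0.0524 to 0.145 over the 3 lists). As a ratio to all genes the stellate, biliary marker (0.422 ratio units per stage) and Notch pathway (0.325) trends passed. With this setting 2 of the 21 list trends that had passed, over all marks, no longer did.

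**Figure D2:**
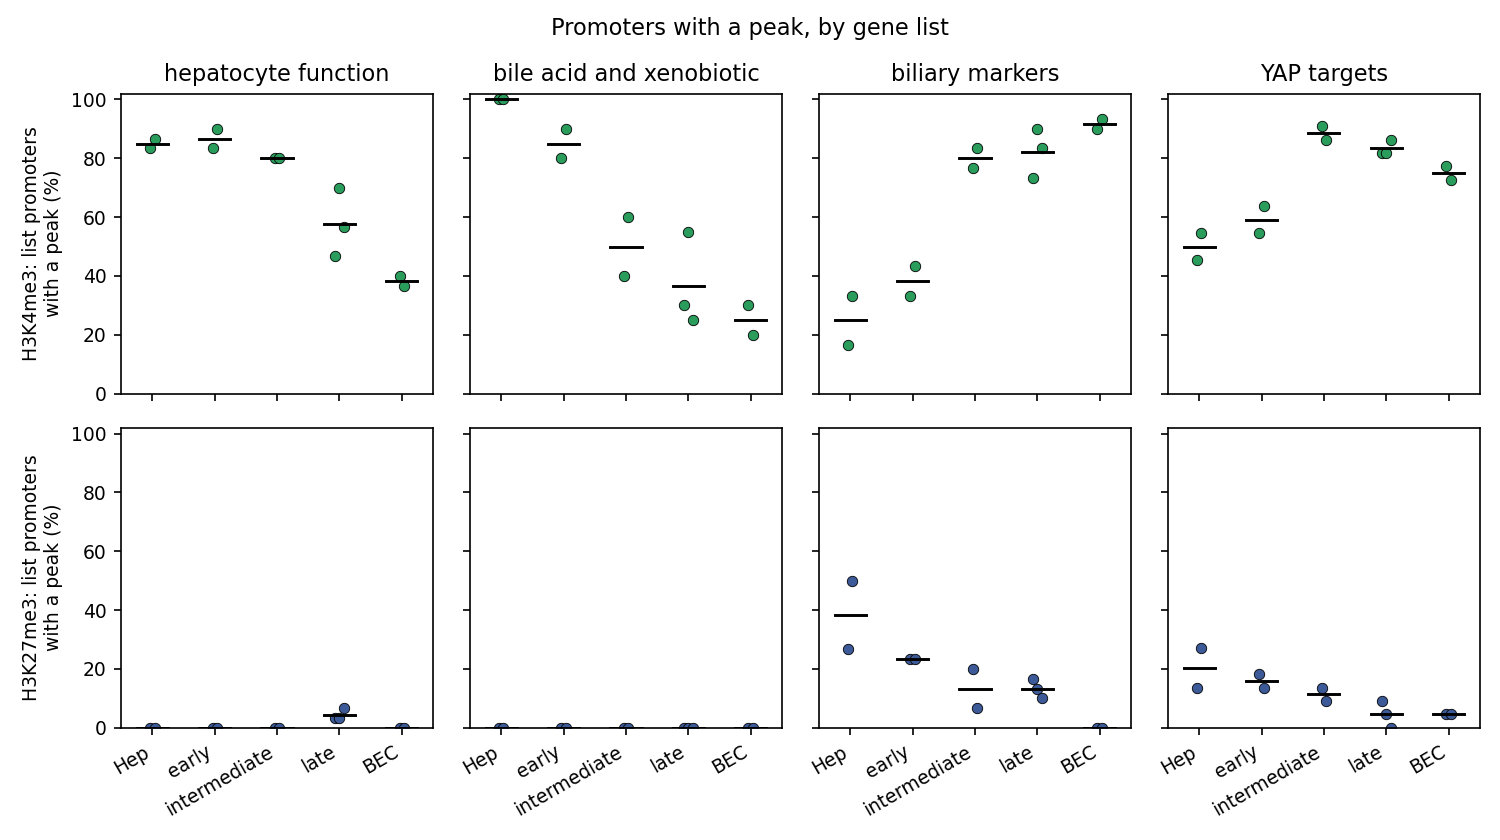
Share of promoters with a peak in 4 gene lists, in percent, for H3K4me3 (upper panels) and H3K27me3 (lower panels) by stage; each dot is a library and each bar a stage mean. Biliary markers go from 25.0% in Hep to 82.2% in late libraries for H3K4me3 and from 38.3 to 13.3% for H3K27me3, and bile acid genes from 100 to 36.7% for H3K4me3.

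The last comparison asked which state promoters left when they gained H3K4me3. Of 21887 protein-coding promoters, 761 had no H3K4me3 within 1000 bp in either Hep library and had it in all 3 late libraries. Among them 168 (22.1%) carried H3K27me3 in both Hep libraries, against 168 of 8179 (2.05%) without H3K4me3 in Hep and late cells (Fisher's exact test across genes, p = 8.43e-94). Of 1127 promoters that had H3K4me3 in BEC and not in Hep 215 (19.1%) carried H3K27me3 in Hep, against 227 of 8592 (2.64%, Fisher's exact test across genes, p = 8.26e-89). Biliary genes in this state in Hep included Sctr, Cldn7, Ddr1, Anxa2 and Anxa3, and the YAP targets Ccn2 and Rbms3. Promoters with both marks in all libraries of a stage numbered 344 in Hep, 90 in early, 318 in intermediate, 120 in late and 23 in BEC, out of 971, 776, 780, 556 and 120 with H3K27me3. These totals set how many can carry both. Late cells needed a peak in 3 libraries and the other stages in 2, which can only lower the late counts. Late 1 is moreover a short-peak library for both marks. Genes are not replicates, and the differences of 20.0 and 16.4 points were 43.8 and 34.8 without Hep 1 and 7.86 and 4.92 with equal numbers of peaks per library. A gain can also reflect the 1000 bp limit. Alb counts as gained in late cells, though its Hep libraries had 287 and 341 bp of H3K4me3 within 2500 bp.

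**Figure D3:**
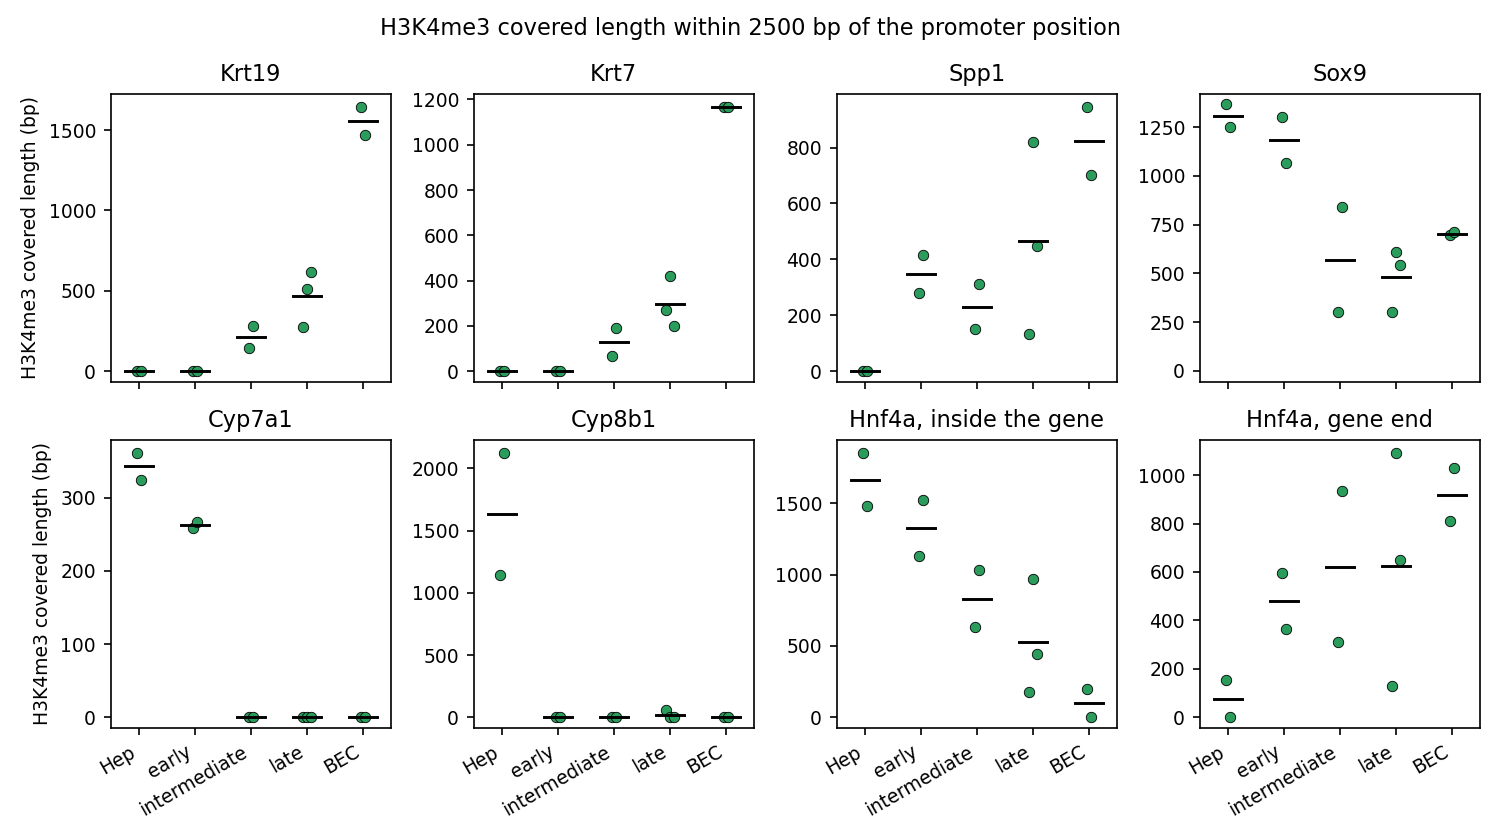
H3K4me3 covered length in bp within 2500 bp of the promoter position of Krt19, Krt7, Spp1, Sox9, Cyp7a1 and Cyp8b1 and of 2 positions of Hnf4a, by stage; each dot is a library and each bar a stage mean. Krt19 has no peak in Hep and early libraries and 1556 bp on average in BEC, while Cyp8b1 has 1632 bp in Hep and none in early libraries.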

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

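Peak lists were compared without reads, so a weak mark and an absent mark look alike. Resized peaks, short-peak libraries left out, gene ends only and H3K4me1 as a ratio were chosen only after the results were seen, and the cause of the shifts below was not tested. The setting planned with the most 5 prime annotated end was not run, since the gene table has no strand. Of 401 passing results for named genes 325 kept their call with quantile normalization, 269 with resized peaks, 310 with 500 bp added and 260 without the filter on promoters. With equal numbers of peaks 265 of 380 kept it and 3 were reversed. Of 21 list trends that passed, 9 did with the list share alone, 16 with resized peaks, 12 with short-peak libraries left out and 20 with gene ends only.

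The within-stage excess of overlap passed for H3K4me3 by share of peaks overlapped (0.0538), with resized peaks (0.0902) and with short-peak libraries left out (0.103). For H3K27me3 it passed with an equal number of peaks (0.0375), the stricter 50% of peaks (0.0258), the share overlapped (0.0644), resized peaks (0.02996) and short-peak libraries left out (0.0315). Leaving out 1 library gave 0.0233 (Hep 2) to 0.0949 (late 2) for H3K4me1, 0.0199 (Hep 2) to 0.107 (late 2) for H3K4me3 and 0.0150 (early 1) to 0.0315 (late 1) for H3K27me3.

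The shift between hepatocyte and biliary regions no longer passed with peaks covering 50% of a region for H3K4me1 (12.2 points per stage) and H3K4me3 (16.9). With short-peak libraries left out it was 30.0 for H3K4me1, 31.6 for H3K4me3 and 35.5 for H3K27ac. There the exact p was the smallest the remaining libraries allow (0.0333, 0.0667 and 0.0222), so the missed threshold follows from their number. For H3K27me3 it ranged from 1.55 without Hep 1 to 13.6 without BEC 2.

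Changed H3K4me3 promoters in early against Hep cells numbered 12 with 500 bp added, 260 after quantile normalization, 189 with trend and robust eBayes, 517 with resized peaks and 361 with short-peak libraries left out. In intermediate against early cells they numbered 115 with equal peaks, 11 with 500 bp added, 410 after quantile normalization, 720 resized and 627 without short-peak libraries. In late against intermediate cells they numbered 33 after quantile normalization, 7 without the filter, 103 resized and 53 without short-peak libraries. In late against Hep cells they numbered 593 with 500 bp added, 247 without the filter, 2169 resized and 2110 without short-peak libraries. In BEC against late cells the counts were 209 with equal peaks, 48 with 500 bp added, 244 after quantile normalization, 397 resized and 534 without short-peak libraries, and in BEC against Hep 670 without the filter.

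Changed H3K27ac promoters in early against Hep cells numbered 1132 with equal peaks, 224 after quantile normalization, 1430 without the filter and 1056 resized. In intermediate against early cells the counts were 270 with equal peaks, 3 with 500 bp added, 153 after quantile normalization, 357 without the filter, 308 with trend and robust eBayes and 1113 resized. In late against intermediate cells they were 1 with the 1000 bp window, 10 after quantile normalization, 34 without the filter, 170 resized and 1 with gene ends only. In late against Hep cells they were 5463 with 500 bp added, 1506 after quantile normalization, 1528 without the filter, 1161 resized and 1803 without late 1, the short-peak library. BEC against late cells gave 158 with equal peaks, 9 with 500 bp added, 56 with the 1000 bp window, 239 after quantile normalization, 150 without the filter, 36 with trend and robust eBayes and 358 resized. BEC against Hep gave 1718 without the filter and 1288 resized.

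Leaving out 1 library at a time, changed H3K4me3 promoters ran from 0 (Hep 2) to 243 (late 1) in early against Hep, 0 (early 1) to 387 (late 1) in intermediate against early, 0 (Hep 1) to 6 (late 1) in late against intermediate, 155 (Hep 2) to 1506 (late 1) in late against Hep, 0 (BEC 1) to 228 (late 1) in BEC against late, and 1009 (Hep 1) to 2090 (late 1) in BEC against Hep. Those of H3K27ac ran from 285 (Hep 2) to 3450 (intermediate 1) in early against Hep, 0 (early 1) to 1213 (early 2) in intermediate against early, 91 (Hep 2) to 3853 (early 1) in late against Hep, 0 (late 3) to 120 (late 1) in BEC against late, and 725 (Hep 2) to 3233 (early 1) in BEC against Hep.

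The number of list trends that passed, of 4 for H3K4me1, 8 for H3K4me3, 5 for H3K27ac and 4 for H3K27me3, changed with the setting. For H3K4me1 it was 7 with equal peaks, 1 with the list share alone, 10 with H3K27ac by neighbourhood, 2 resized and 2 without short-peak libraries. For H3K4me3 it was 4 with the list share alone and 5 without short-peak libraries. For H3K27ac it was 8 with the wider window, 3 with the list share alone and 12 by neighbourhood. For H3K27me3 it was 10 with equal peaks, 1 with the list share alone and 2 without short-peak libraries. Leaving out 1 library gave 1 (Hep 1) to 11 (early 1) for H3K4me1, 5 (Hep 1) to 8 (late 2) for H3K4me3 and 0 (Hep 2) to 5 (early 1) for H3K27me3.

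Some results changed sign. Of the list trends these were macrophage H3K4me1 with the list share alone (−0.1145 points per stage), stellate H3K27ac by neighbourhood (0.370, which passed) and NRF2 and stress H3K27me3 with equal peaks (0.420). With gene ends only, the log2 change was −0.444 at Klhl3 (H3K4me3, BEC against late), 2.67 at Hnf4a and 3.08 at Ikbke (H3K4me3, BEC against Hep). For H3K27ac it was 2.36 (intermediate against early), 0.61 (BEC against late) and 1.90 (BEC against Hep) at Hnf4a, 0.214 at Creb3l3 (late against Hep) and −1.07 at Igsf23 (BEC against Hep). H3K4me3 at Maml2 was −0.709 with the 1000 bp window (BEC against Hep). H3K27ac was 0.059 at Ggt1 after quantile normalization (early against Hep). With equal peaks it was 0.135 and 0.486 at Ppara (early and late against Hep) and 0.515 at Hey1 (late against Hep). Resized peaks gave 0.175 at Amotl2 and 0.527 at Dock5 (late against Hep).

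By the median, replicate numbers did not pair the libraries. Over 20 pairs of libraries per mark with the same number the median correlation after removing stage was −0.0144 for H3K4me1, 0.0264 for H3K4me3, −0.0201 for H3K27ac and −0.0126 for H3K27me3. In stages of 2 libraries the deviations mirror each other, so some pairs repeat the same value and the 20 are not separate. Above 0.1 were 3 pairs for H3K4me3 (highest 0.216, intermediate 1 and late 1), 2 for H3K4me1, 1 for H3K27ac and 0 for H3K27me3. With a replicate block the overlap excess of H3K4me3 was 0.0521 and passed, and the position shifts were 26.9, 28.8 and 34.7 points for H3K4me1, H3K4me3 and H3K27ac. The block leaves 36 arrangements and a smallest exact p of 0.0556, so no position shift could pass. With the replicate block the H3K4me3 counts were 274 (early against Hep), 342 (intermediate against early) and 298 (BEC against late), and those of H3K27ac 227 (intermediate against early), 1073 (late against Hep) and 0 (BEC against late). List trends that passed with it numbered 1 for H3K4me1, 2 for H3K4me3 and 0 for H3K27me3, where the smallest exact p is 0.00347.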

Other observations

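Hnf4a, a hepatocyte regulator on chromosome 2 (163506811 to 163572907), carried H3K4me3 at 2 positions whose covered length moved in opposite directions, a comparison chosen after the values were seen. Whether transcription starts at either position was not tested. At the position inside the gene (163548465) covered length was 1664 ± 265 bp in Hep, 1326 ± 279 in early, 830 ± 285 in intermediate, 530 ± 402 in late and 99.5 ± 141 in BEC libraries (BEC against Hep log2 −3.34, adjusted p = 0.00271). At the gene end (163506811) it was 76 ± 108 bp in Hep, 479 ± 163 in early, 622 ± 441 in intermediate, 623 ± 483 in late and 920 ± 156 in BEC libraries (log2 2.67, adjusted p = 0.0207). H3K27ac inside the gene went from 732 ± 183 bp in Hep to no peak in BEC (adjusted p = 0.0016), and at the gene end from 61 ± 86.3 to 464 ± 127 bp (log2 1.90, adjusted p = 0.0243). No library had H3K27me3 at either position.

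A few biliary and YAP genes, picked after the values were seen and not tested across stages, differed in the last stage with an H3K27me3 peak. Ddr1 and Anxa2 had H3K27me3 and no H3K4me3 in both Hep libraries and the reverse in both early libraries. Ccn2 had H3K4me3 in 2 of 2 early libraries with H3K27me3 still in 1, and no H3K27me3 in any intermediate, late or BEC library. Anxa3 held H3K27me3 in 2 of 2 early libraries and first had H3K4me3 in intermediate ones. Klf5 carried both marks in every Hep, early and intermediate library and kept H3K27me3 in 2 of 3 late ones. Sctr, which had no H3K4me3 in Hep or early libraries, also had H3K27me3 in 2 of 3 late ones, and Rbms3 had it in 1 of 3. Absent H3K27me3 in BEC is not read as a loss here, since the BEC lists hold few H3K27me3 peaks.

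The tests of isolation and of promoter placement below were chosen only after the result was seen, and the others were chosen before their values were computed. H3K27ac covered less of many promoters in early than in Hep cells. Fewer and shorter called peaks could cause this. With the same number of peaks of one width in every library 424 promoters were lower and 170 higher (71.4% lower), against 3245 and 128 with the listed peaks. This lies between the 60% and 75% set for a decision. Gradient isolation from untreated mice against sorting after the diet stays open: 9 of 9 sorted libraries covered fewer bases (5.74 to 13.1 Mb) than both Hep libraries, but isolation, diet and stage change together and cannot be told apart.

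Other groupings of the H3K4me3 libraries, unrelated to stage, called up to 10508 promoters. Short called peaks in 2 libraries might cause this in part. Of 7 groupings with over 1000 calls 57.1% put both in one stage, and these 4 had at least 5677 calls against at most 1179 with the 2 apart, while 3 of the 7 groupings that put them together called 0. A structure of the libraries apart from peak length did not account for the highest counts, since resizing lowered these 4 to 541 to 1490 and the highest count of any grouping to 1579. It was not excluded for smaller counts, since 82 of 99 groupings called more promoters when resized and 3 called over 1000.

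Of 100 groupings of the libraries, the real one included, as many H3K4me3 calls or more came in 8 for early against Hep (109 calls), 10 for intermediate against early (36), 8 for BEC against late (102), 2 for late against Hep (906) and 3 for BEC against Hep (1801). For H3K27ac they came in 6 for BEC against late (90, highest other 4874), 2 for intermediate against early (717) and 1 each for early, late and BEC against Hep. The highest other H3K4me3 counts were 8232 for late against Hep and 8678 for BEC against Hep. Chance was therefore not excluded for any H3K4me3 count, nor for H3K27ac in BEC against late or intermediate against early. In the other 3 H3K27ac contrasts with calls only the real grouping reached its count, the fewest that 100 groupings allow.

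Promoters that gained H3K4me3 in late cells often carried H3K27me3 in Hep. The test of being able to carry H3K4me3 in any stage could not decide whether that accounts for it. Of 438 promoters with H3K4me3 only in early, intermediate or BEC libraries 7.31% carried H3K27me3 in Hep. That share lies above the 2.05% of promoters without H3K4me3 in Hep and late cells and below the 22.1% of gained ones. An H3K4me3 peak in any of these libraries was enough for the 438, while gained promoters needed a peak in every late library. Peaks called in few libraries may therefore have lowered the 7.31%. Whether placing the promoter by its H3K4me3 plays a part was not decided. With H3K27me3 counted at the promoter position or either gene end the difference was 21.1 points (23.8% against 2.64%). That count can only raise the share of the gained promoters, and many promoters without H3K4me3 already had both ends counted. H3K4me3 taking the place of H3K27me3 was not decided either. Of the gained promoters with H3K27me3 in Hep 42.3% had no H3K27me3 peak in any late library, against 8.33% of those without gain (Fisher's exact test across genes, p = 3.87e-13). The other gained promoters still had an H3K27me3 peak in late cells. Late peaks were thus missing more often after a gain, but a missing H3K27me3 peak does not show that the mark was absent. Genes are also not replicates.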
